A study of Homo sapiens with 4 samples.

How the data were processed

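The series holds 4 GLORI libraries of HEK293T messenger RNA, 2 from control cells and 2 from cells given ascorbic acid for 36 h after 24 h of seeding, per the labels. The dose is not given in the sources used here. Per the labels' protocols, 300 ng of mRNA was fragmented, protected with glyoxal, deaminated for 8 h at 16 °C, deprotected and made into libraries. The submitters' processing notes name Trimmomatic 0.39, STAR and the builds hg38 and GRCh38; the program that called sites and its settings are not given in the sources used here.

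Each library came as its own table of called sites, with position, strand and gene. The whole read counts per site, for A plus G and for A alone, are the authors' counts and were deposited without scaling. The m6A level is a fraction that the authors gave as A over A plus G, and recomputing it matched in every entry within 6e-06. The conversion rate is a second fraction made by the authors, 1 value per gene or, for sites in no named gene, per chromosome. The gene coverage is a signal as deposited by the authors, taken from its header and values as a mean per gene not scaled for depth, but no source defines its unit. The p-value and adjusted p-value of each site are the authors' test of the site against background, per the file headers. The lists hold no site under 15 A plus G reads, 5 A reads or a level of 10%, and the largest adjusted p per list lies between 0.00401 and 0.00404. A site below these limits in a library is not listed there and could not be compared. Losses to under 10% are therefore not among the falls, and gains from under 10% in control are not among the rises. No per-sample column outside these 4 libraries was used.

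Of 15209 gene names, 14475 matched a symbol of the RefSeq gene table (GRCh38.p14) and 284 a synonym, while 450 did not match. Coordinates are the authors' positions, and gene spans, biotypes and 3' ends come from that table, which is on the same build. No genome sequence or transcript annotation was at hand. The planned split by transcript region and sequence motif, and the setting with sites in the usual DRACH motif alone, were therefore not run, and gene biotype and distance to the annotated 3' end of the gene took their place. Of the tested sites, 173 lay on alternate or unplaced contigs.

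The designs, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Sites listed in all 4 libraries with at least 20 A plus G reads in each were tested with edgeR 4.0.16 by its quasi-likelihood test on A and G reads, with a term for each library and a treatment effect on the odds of A. The same test was run on A and G reads summed over the tested sites of a gene; a read that covers several sites counts at each. Gene coverage was scaled per library by the median ratio to the geometric mean over genes and tested with limma 3.58.1 (trended eBayes on log2 values). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, two-sided. Of the 19 lists fixed, the 17 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 on log2 odds with 0.5 added to A and G, and again with an estimated correlation. Group medians of the libraries were compared by an exact permutation test. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were the other tools.

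Named sites are the 10 largest falls and 10 largest rises in mean level, with each gene's site of smallest p as its only candidate, among sites past the threshold with at least 50 reads in every library and groups that do not overlap; 15995 falls and 126 rises met the terms on threshold, reads and overlap, before 1 site per gene was taken. Named genes are the 5 largest falls and 5 largest rises in log odds past the threshold with at least 3 tested sites, and for coverage the 5 largest rises and falls past the threshold. Up to 4 members of each list with the smallest p could be named, and FTO, ALKBH5, METTL3, METTL14, WTAP and MALAT1 were always reported. The single FTO site was named after its values were seen.

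The lists were m6A writers, m6A readers, nucleic acid dioxygenases, JmjC dioxygenases, the hypoxia pathway and its targets, collagen hydroxylation and folding, iron handling, ascorbate transport and recycling, the antioxidant response, p53 targets, the unfolded protein and integrated stress response, transcripts often studied as m6A targets, cholesterol synthesis, the cell cycle, nuclear long noncoding RNAs, markers of other cell types, ZNF genes, cytosolic ribosomal proteins and mitochondrially encoded genes. Some genes stand in more than 1 list.

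Each test was tried on simulated data made from the real depths with 100 items changed at each size. Of the changed items as many rose as fell. In the real data 20313 sites passed and nearly all fell, and the Benjamini-Hochberg cutoff on p moves with such numbers. The simulated shares and false calls are therefore not those of the real site and gene tests. For sites, 35% of log2 odds changes of 1 and 67% of changes of 2 were recovered among 78509 sites, with 3 false calls. For genes, 83% and 93% were recovered at the same sizes among 10782 genes, with 6 false calls. For coverage, 96% of log2 changes of 0.5 and 100% of changes of 1 were recovered among 11848 genes, with 9 false calls. On the real A and G reads the chi-square per site between replicates was 1.16 in control and 1.03 with ascorbic acid, where counting error alone gives about 1.

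Alternatives covered the coverage minimum, the test, subtraction of the unconverted share, the level and site filters, the replicate number as a block, scaling and filters of coverage, and each library left out in turn. Settings added after the data were seen left out sites with a listed site 6 nt away, sites in no named gene or sites on other contigs, crossed the pairing for coverage, and used other sets for the conversion rate.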

Results

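N6-methyladenosine (m6A) was measured in messenger RNA of HEK293T cells, a human embryonic kidney line, with or without ascorbic acid. The assay was GLORI, in which glyoxal and nitrite convert unmethylated adenosine so that it is read as G, while m6A is still read as A. The m6A level of a site is therefore the percent of its reads that carry A. The series holds 2 control libraries and 2 ascorbic acid libraries, and treatment for RNA lasted 36 h with a medium change every 6 h, per the labels' protocols. The labels do not say that the replicates were separate cultures, so the p-values cover no more than the spread between these 4 samples. For site levels that spread was close to counting error (chi-square per site between replicates 1.16 in control and 1.03 with ascorbic acid). Fisher's exact test on pooled reads, which ignores the libraries, called 21364 sites and shared 19961 calls with the edgeR test in the same direction. The p-values of sites thus rest largely on read counts. Each library came with its own list of called sites, 132989 and 144171 sites in the control libraries and 135205 and 143518 with ascorbic acid. The A plus G reads at listed sites came to 22592887 and 28562744 in the control libraries and to 25146378 and 26816350 with ascorbic acid. Sites listed in all 4 libraries with at least 20 reads in each could be compared, which left 78509 sites, of which 7031 lay in no named gene and the others in 10782 genes. The median depth of these sites was 97 and 100 reads in control and 102 and 118 reads with ascorbic acid. Coordinates are on GRCh38. Whether repeated reads of 1 molecule were removed is not given in the sources used here, so the reads behind a level are not counted as independent molecules.

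The question of the series is whether ascorbic acid, which recycles Fe(III) to Fe(II) for dioxygenases such as the m6A demethylases FTO and ALKBH5, changes the methylation of RNA. m6A was lower with ascorbic acid at most of the sites compared. The median level over the tested sites was 40.9% ± 1.23 in control and 33.9% ± 0.113 with ascorbic acid (SD, n = 2 per group), so that it fell by 7.04 percentage points. The mean level went from 47.6% to 40.6%. The library medians were 40.1% and 41.8% in control against 34.0% and 33.8% with ascorbic acid, so the groups lay further apart than the replicates of either. With 2 libraries against 2 the exact two-sided permutation p was 0.333, the smallest that this design allows. Over each library's own list, where the sites differ, the medians were 32.6% and 29.4% in control and 28.3% and 28.2% with ascorbic acid, a difference of -2.79 points, so there the control libraries lay further apart from each other than the group means. The level was lower with ascorbic acid at 82.9% of the tested sites, by any amount. Both ascorbic acid libraries lay below both control libraries at 55.4% of sites and above both at 4.22%, where chance gives 16.7% each way. The deposited conversion rates leave a median unconverted share over genes of 2.51% and 3.88% in the control libraries and of 2.72% and 2.87% with ascorbic acid, so control 2 stood apart and control 1 lay below both treated libraries.

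**Figure D1:**
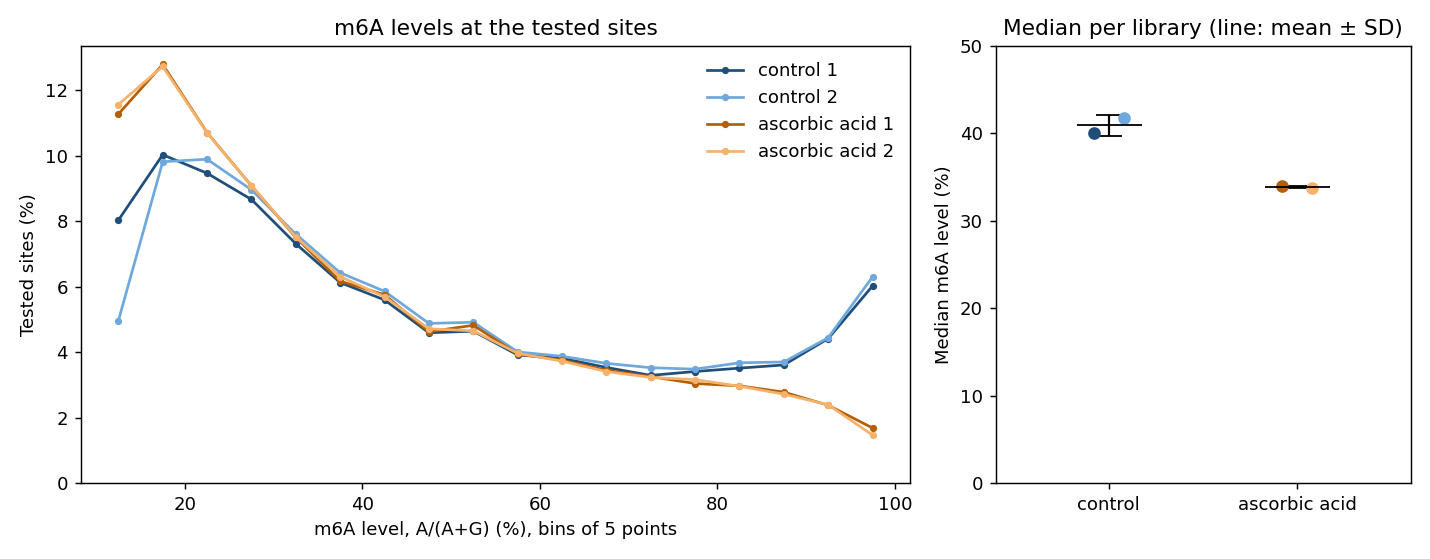
The left panel plots the percent of the 78509 tested sites (y axis) in each 5-point bin of m6A level (x axis, percent) for each of the 4 libraries. The right panel plots the median level per library, with a line and bar for the mean and SD of n = 2: 40.9% ± 1.23 in control and 33.9% ± 0.113 with ascorbic acid.

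Single sites answered which positions changed. By edgeR's quasi-likelihood test on A and G reads, 20141 sites fell (25.7% of those tested), 172 rose (0.219%) and 58196 did not pass at an adjusted p of 0.05. The sites that fell had a median level of 71.0% in control and 47.6% with ascorbic acid. Their median change per site was -14.8 points, and 6337 of them fell by more than 20 points. The largest fall was in TANGO6, a gene for a protein of Golgi organisation, at chromosome 16 position 68860219, from 82.4% ± 4.79 to 14.5% ± 2.22 (141 to 267 reads per library, edgeR adjusted p = 3.13e-19). A site of PIAS2, a SUMO ligase gene, at chromosome 18 position 46890866 fell from 78.3% ± 0.639 to 13.1% ± 3.70. The deepest of the 10 named falls was in SUGP2, whose protein has a domain of splicing factors, at chromosome 19 position 19024896. That site went from 77.9% ± 0.923 to 15.8% ± 0.780 with 611 to 873 reads per library (edgeR adjusted p = 2.89e-26). MYO9B, an unconventional myosin gene, fell at chromosome 19 position 17102157 from 85.7% ± 5.60 to 21.6% ± 0.496. CPLANE1, a gene of cilium formation, fell at chromosome 5 position 37168950 from 78.3% ± 4.71 to 16.1% ± 0.321.

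Of the other named falls, ESPL1, the gene of separase, which cleaves cohesin, fell at chromosome 12 position 53270010 from 80.9% ± 2.73 to 19.6% ± 0.625. PLXNB2, a semaphorin receptor gene, fell at chromosome 22 position 50290014 from 81.3% ± 1.499 to 20.2% ± 2.08. EHMT1, a histone methyltransferase gene, fell at chromosome 9 position 137717030 from 83.2% ± 2.72 to 22.3% ± 2.21. ASCC3, a helicase gene, fell at chromosome 6 position 100848635 from 76.1% ± 10.8 to 15.4% ± 3.13. NF1, the gene of a Ras GTPase-activating protein, fell at chromosome 17 position 31325954 from 80.6% ± 3.32 to 19.9% ± 5.25. All 10 sites passed in every alternative setting that tested them, and all lay at least 15035 nt from the annotated 3' end of their gene.

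The sites that rose were few and of low level, with a median of 13.9% in control and 18.9% with ascorbic acid, and 7 of them rose by more than 20 points. Among named sites with at least 50 reads, the largest rise was in NUDT5, a nucleotide hydrolase gene, at chromosome 10 position 12166481, from 17.9% ± 5.53 to 34.3% ± 2.79 (edgeR adjusted p = 0.0227). FOXB1, a transcription factor gene, rose at chromosome 15 position 60006030 from 54.2% ± 0.452 to 68.4% ± 6.86. IREB2, the gene of an iron regulatory protein, rose at chromosome 15 position 78501142 from 18.8% ± 5.02 to 32.7% ± 5.85. NDUFS5, a gene of respiratory complex I, rose from 34.3% ± 2.12 to 48.1% ± 0.786 at chromosome 1 position 39026318, which lies before the annotated gene start at 39026350. SERF2 rose at chromosome 15 position 43792320 from 21.7% ± 9.06 to 35.6% ± 6.19. DIXDC1 rose at chromosome 11 position 112019740 from 26.3% ± 4.19 to 40.1% ± 0.721, and BCAR1, an adhesion adaptor gene, at chromosome 16 position 75235250 from 33.4% ± 2.77 to 47.0% ± 5.99. SEPHS2P1, a pseudogene whose reads can belong to its parent gene, rose at chromosome 5 position 14960840 from 40.5% ± 4.20 to 53.5% ± 1.75. MRPL33, a mitochondrial ribosome gene, rose at chromosome 2 position 27779500 from 19.8% ± 0.903 to 31.8% ± 3.95. MEPCE, the capping enzyme gene of the 7SK RNA, rose at chromosome 7 position 100430819 from 20.5% ± 3.11 to 32.3% ± 1.99. None of these 10 rises passed with limma or DESeq2, and 124 of the 172 sites that rose (72.1%) had another listed site exactly 6 nt away on the same strand, SERF2 included. Without such sites 56 rose and 20063 fell; with limma 25 rose and 10476 fell, with DESeq2 14 and 9837, and without ascorbic acid 1 or ascorbic acid 2 the sites called numbered 13505 and 12528.

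**Figure D2:**
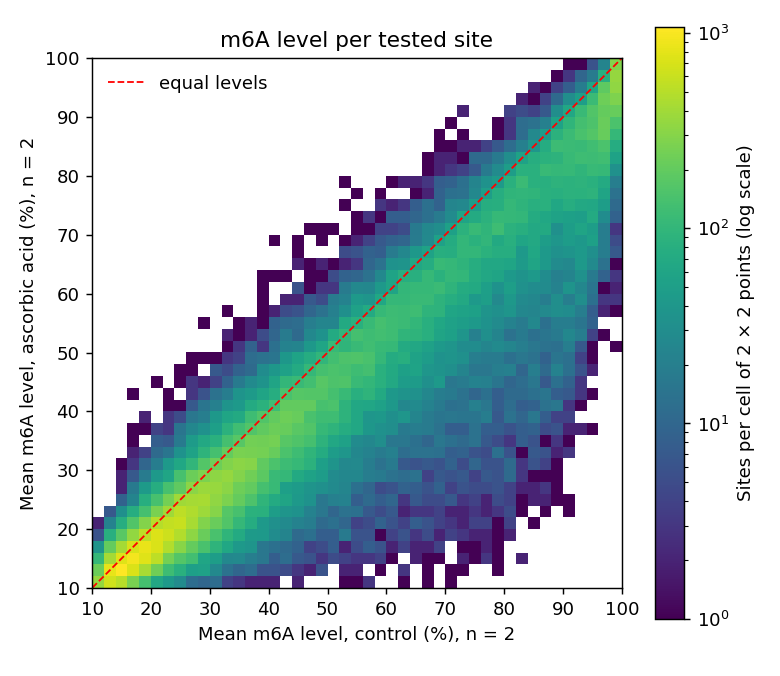
Mean m6A level of each tested site in control (x axis, percent, n = 2) against that with ascorbic acid (y axis, percent, n = 2), coloured by the number of sites per cell on a log scale. The dashed line marks equal levels, and 82.9% of the sites lie below it.

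**Figure D3:**
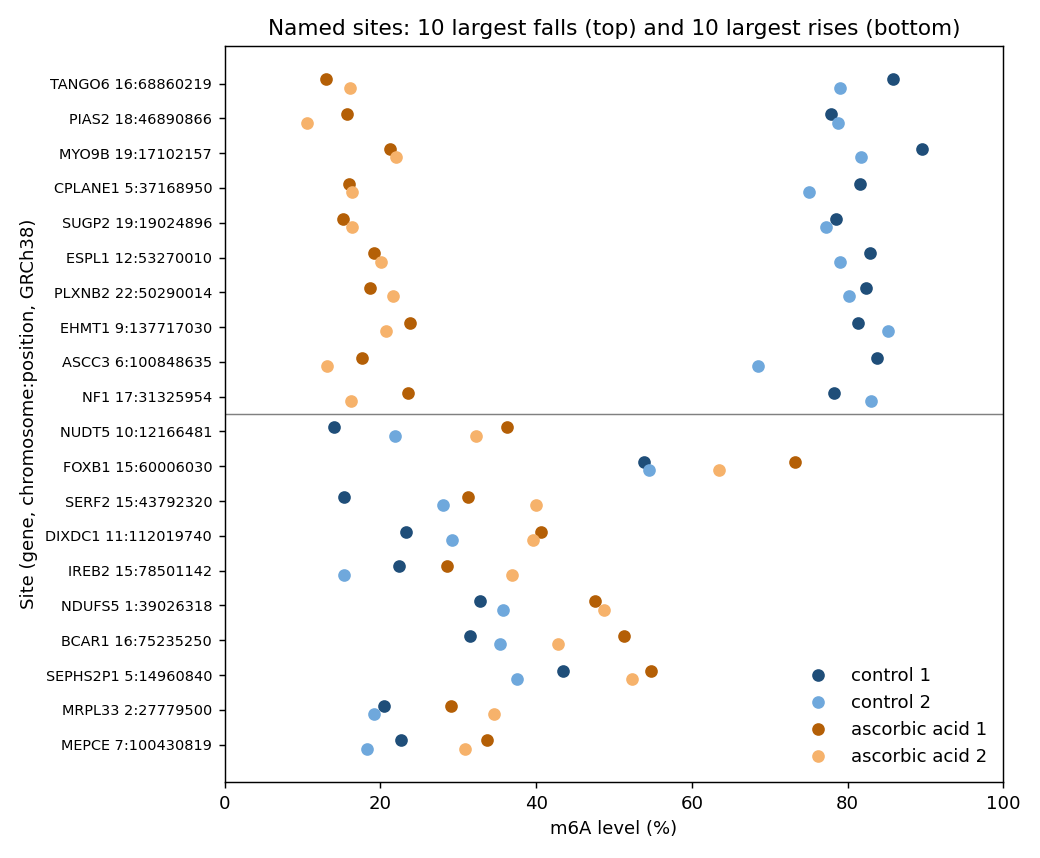
m6A level (x axis, percent) of the 20 named sites (y axis) in each library, with 10 falls above the grey line and 10 rises below it. At every named site the 2 control points and the 2 ascorbic acid points do not overlap, and the smallest of the named falls is from 80.6% to 19.9%.

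Summed over the tested sites of each gene, 6114 genes fell, 32 rose and 4636 did not pass among 10782 genes (edgeR, adjusted p of 0.05), and 92.3% were lower by any amount, with a median change of -0.39 in log2 odds. The largest gene-level falls were in PIAS2, from 74.2% ± 2.87 to 22.9% ± 2.33 over 3 sites (log2 odds -3.28), and ZDHHC6, a palmitoyltransferase gene, from 82.4% ± 1.67 to 36.2% ± 1.38 (-3.04). CPLANE1 fell from 60.2% ± 0.975 to 16.9% ± 0.268 (-2.90), and ROBO2, a gene of an axon guidance receptor, from 52.6% ± 2.34 to 17.0% ± 1.64 (-2.44). LOC729033, a pseudogene that can share reads with its parent gene, fell from 91.1% ± 1.73 to 63.1% ± 6.18 (-2.48). The largest rises were in GSTA4 (0.53), POLD1 (0.50), ATIC (0.47), CERS2 (0.41) and TRA2B (0.41), all in log2 odds. These rises turned to -0.71, -0.65, -0.31, -0.59 and -0.60, in the same order, when sites with a listed site 6 nt away were left out, and with that setting 10 genes rose. Without ascorbic acid 1, 16 genes rose, without ascorbic acid 2, 50, and without control 2, 98.

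The transcripts of the demethylases FTO and ALKBH5 and of the methyltransferase subunits METTL3, METTL14 and WTAP fell in m6A level. FTO fell from 28.9% ± 1.90 to 17.5% ± 0.0462 over 6 sites (edgeR adjusted p = 1.61e-06), with its largest fall at chromosome 16 position 53826315, from 73.1% ± 5.51 to 18.8% ± 1.40 on 39 to 90 reads. METTL3, the catalytic subunit, fell from 45.3% ± 0.0993 to 28.5% ± 0.286 (adjusted p = 1.27e-07, edgeR). METTL14 fell from 51.2% ± 2.004 to 43.4% ± 2.63, WTAP from 38.6% ± 0.988 to 33.7% ± 0.151, and ALKBH5 from 32.2% ± 2.36 to 28.4% ± 2.01 (edgeR adjusted p = 0.0116). MALAT1, a nuclear long noncoding RNA, had 1 tested site, which fell from 28.3% ± 4.65 to 13.4% ± 0.369 on 38 to 61 reads. The ALKBH5 call was lost without ascorbic acid 2 (adjusted p = 0.317) and the MALAT1 call without control 1 (0.111), ascorbic acid 1 (0.0688) or ascorbic acid 2 (0.123), all by edgeR. With limma on log odds ALKBH5 (adjusted p = 0.192), METTL14 (0.0582) and WTAP (0.0643) did not pass, and with no read minimum beyond the authors' MALAT1 did not pass by edgeR (0.132).

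Groups of genes answered whether the loss followed a pathway, and every list with measured genes held some that fell. Over all 10782 genes 56.7% fell, so a count near or below that share marks no loss particular to its list. The share was larger among genes with at least 3 tested sites, where 5173 of 7236 fell. A count above 56.7% can therefore also follow from more sites per gene, for which the lists were not matched. Of the m6A writers 7 of 11 measured genes fell and 4 did not pass, also 7 when adjusted over the list alone, with VIRMA from 45.5% ± 3.27 to 34.2% ± 0.710 and PCIF1 from 63.2% ± 0.321 to 52.1% ± 1.09. Of the readers 9 of 17 fell (9 adjusted over the list alone), among them IGF2BP3, from 40.8% ± 3.81 to 22.0% ± 0.494, IGF2BP1, from 23.5% ± 1.26 to 17.6% ± 0.193, and YTHDF2, from 66.0% ± 1.07 to 59.3% ± 0.567. Of the dioxygenases that act on nucleic acids 7 of 12 fell (7 adjusted over the list alone), with ALKBH2 from 58.2% ± 3.51 to 44.7% ± 1.32 and TET1 from 63.4% ± 3.48 to 52.5% ± 1.11. Among the JmjC dioxygenases, mostly histone demethylases, 19 of 23 fell (19 adjusted over the list alone), with KDM6A from 51.3% ± 0.526 to 31.1% ± 0.216 and KDM5C from 56.6% ± 2.08 to 40.4% ± 0.254. The camera test against all other genes did not pass for this list (adjusted p = 0.133).

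The collagen list, which holds prolyl and lysyl hydroxylases that need ascorbate, chaperones and collagen chains, lost m6A at most of its genes. In it 17 of 21 genes fell (17 adjusted over the list alone), and camera gave an adjusted p of 0.0278 for a larger fall, but adjusted p = 0.942 with an estimated correlation. COL6A1 fell from 59.9% ± 1.82 to 28.9% ± 1.29, COL18A1 from 42.6% ± 1.59 to 17.6% ± 0.763, COL5A1 from 66.5% ± 1.24 to 47.3% ± 1.28 and COLGALT1, a collagen galactosyltransferase gene, from 39.0% ± 2.21 to 26.2% ± 0.578. The camera call was lost without control 1 (adjusted p = 0.138) or ascorbic acid 2 (adjusted p = 0.0867). Cytosolic ribosomal protein genes stood at the other end: 24 of 79 fell, 2 rose and 53 did not pass (23 and 2 adjusted over the list alone). Camera called their fall smaller than that of other genes (adjusted p = 0.000233, and adjusted p = 0.942 with an estimated correlation), with a negative median (-0.24) and mean (-0.26) in log2 odds. RPL41 fell from 63.3% ± 0.175 to 50.1% ± 0.190 and RPL13A from 52.1% ± 0.906 to 39.8% ± 0.332, but the list includes pseudogenes such as RPS24P8 and RPL41P5, so its reads can be shared between copies.

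In the metabolic and stress lists some members fell, against 56.7% of all genes, and camera passed for none of these lists. In iron handling 12 of 23 genes fell (12 adjusted over the list alone), with NFS1, the cysteine desulfurase of iron-sulfur cluster assembly, from 68.9% ± 1.06 to 38.7% ± 0.845, the mitochondrial iron carrier SLC25A28 from 66.0% ± 0.102 to 36.8% ± 1.51 and HMOX2 from 59.2% ± 0.580 to 43.0% ± 0.358. In ascorbate transport and recycling 9 of 12 fell (9 adjusted over the list alone), such as CYB561D2, from 71.0% ± 0.909 to 54.5% ± 1.87, and P4HB, from 46.2% ± 1.14 to 36.0% ± 0.429. In the hypoxia list 12 of 29 fell (12 adjusted over the list alone), with HIF1A from 41.9% ± 3.73 to 31.6% ± 2.14 and VEGFA from 66.7% ± 2.05 to 55.6% ± 0.934. In the antioxidant response 6 of 18 fell (5 adjusted over the list alone), such as TXNRD1, from 36.2% ± 0.564 to 29.8% ± 0.893. Of p53 targets 14 of 19 fell (14 adjusted over the list alone), with DDB2 from 33.2% ± 0.904 to 20.6% ± 0.00826. Of the unfolded protein and integrated stress response 9 of 22 fell (9 adjusted over the list alone), with HSP90B1 from 20.7% ± 0.414 to 12.2% ± 0.0711. In cholesterol synthesis 13 of 20 fell (14 adjusted over the list alone), with FDPS from 33.1% ± 1.51 to 13.8% ± 1.44 and the regulator SREBF1 from 68.3% ± 3.71 to 45.1% ± 0.844.

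In the cell cycle list 21 of 30 genes fell (23 adjusted over the list alone), with the kinase PLK1 from 39.2% ± 1.35 to 28.2% ± 0.220 and TOP2A from 36.5% ± 2.31 to 27.3% ± 0.642. Of transcripts often studied as m6A targets 8 of 23 fell (6 adjusted over the list alone), with LATS1 from 47.6% ± 0.720 to 36.8% ± 0.229 over 33 sites and RARA from 56.3% ± 1.98 to 45.8% ± 0.0723. Of nuclear long noncoding RNAs 4 of 6 fell (4 adjusted over the list alone), with TUG1 from 40.5% ± 0.275 to 35.8% ± 0.0360 over 72 sites. Of ZNF genes 121 of 270 fell (115 adjusted over the list alone), such as ZNF276, from 53.9% ± 0.816 to 34.7% ± 1.33, and ZNF638, from 59.2% ± 1.77 to 40.7% ± 1.27. Apart from the 2 ribosomal protein genes no member of any list rose by edgeR, and apart from the collagen and ribosomal lists no camera test passed over the 17 lists tested (adjusted p from 0.133 to 0.995). Markers of other cell types and genes with the MT- prefix had no measured gene.

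Site classes answered where in genes the loss was largest, and among protein-coding genes it was largest far from the gene's 3' end. Protein-coding genes fell by 7.46 points at the median, from 41.0% ± 1.21 to 33.5% ± 0.248, long noncoding RNA genes fell by 6.58 points, from 46.6% ± 1.64 to 40.0% ± 0, and sites in no named gene fell by 4.76 points, from 40.2% ± 1.07 to 35.4% ± 0.134. Within protein-coding genes, sites less than 1000 nt from the annotated 3' end of their gene fell by 6.69 points, those at 1000 to 5000 nt fell by 6.12 points and those beyond 5000 nt fell by 9.34 points. The classes also differ in level, so protein-coding sites at 60 to 90% in control were compared. Their median went from 74.7% ± 0.723 to 62.6% ± 0.0746 within 1000 nt of the end, from 75.0% ± 0.638 to 65.2% ± 0.0986 at 1000 to 5000 nt, and from 75.5% ± 0.655 to 62.8% ± 0.502 at 5000 to 20000 nt. Beyond 20000 nt it went from 75.7% ± 0.930 to 55.2% ± 0.316, and 14.4% of those 2576 sites fell by more than 40 points, against 1.58% to 3.50% in the nearer classes. Without a transcript annotation these sites could not be placed in exons or introns. The median beyond 20000 nt minus that of the nearer sites was 0.439 and 0.830 points in the control libraries and -8.60 and -8.90 points with ascorbic acid, so the groups lay further apart than the replicates, with an exact two-sided permutation p of 0.333, the smallest that this design allows.

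**Figure D4:**
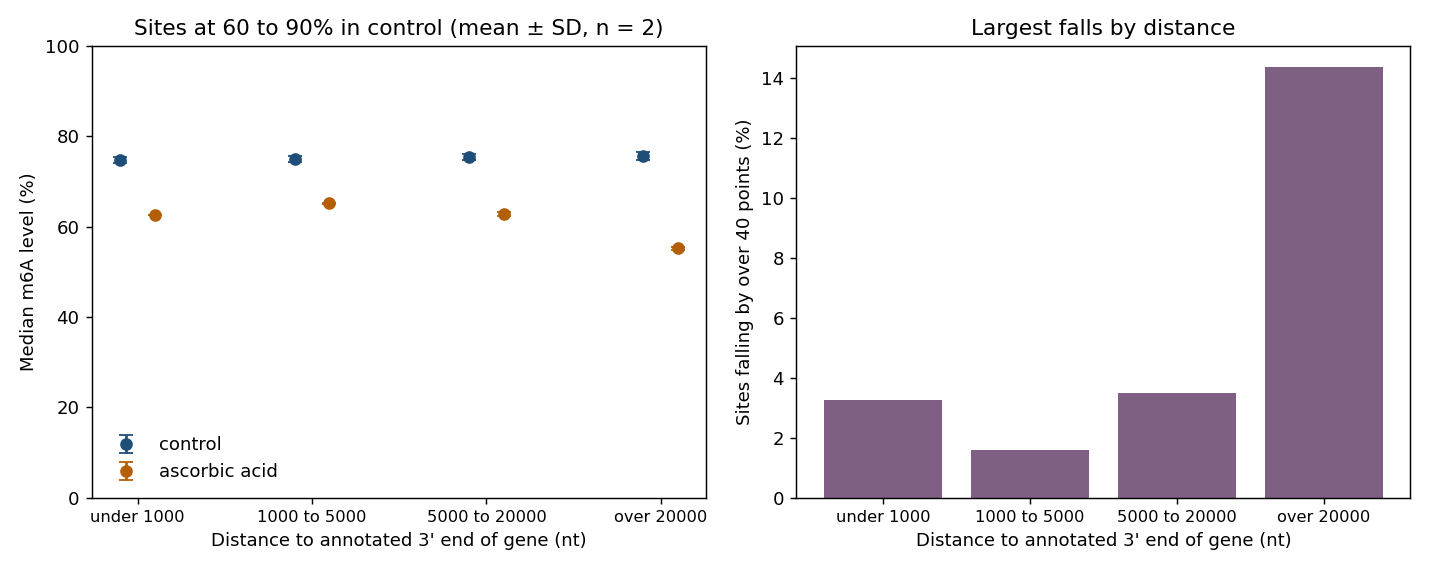
Left, median m6A level (y axis, percent, mean ± SD, n = 2 per group) of sites at 60 to 90% in control, by distance to the annotated 3' end of their gene (x axis, nt). Right, the percent of these sites that fell by more than 40 points in the same classes, 14.4% beyond 20000 nt and at most 3.50% nearer.

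As listed, the ascorbic acid lists lay between the control lists in size, with group means of 138580 and 139362. Both control libraries and no ascorbic acid library listed 6664 sites, while 6026 were listed in both ascorbic acid libraries only. Thinned to equal total reads at the tested sites, these numbers were 7249 and 4971, and both ascorbic acid libraries listed fewer sites (131348 and 130252) than both control libraries (132989 and 137441). Thinning can only remove listed sites. Control 1 kept all its reads, control 2 a share of 0.920 and the ascorbic acid libraries 0.961 and 0.854, so part of this order may follow from the thinning. At levels of at least 0.2 the ascorbic acid libraries also listed fewer, 88486 and 94313 against 94545 and 97474. The other splits of the libraries into pairs gave 3559 to 5222 sites listed in 1 pair only, without thinning, and an exact permutation test cannot go below 0.333 with this design. Control-only sites had a median level of 16.1% on 76.5 reads, ascorbic-acid-only sites 22.1% on 37.5 reads. Listed sites lay exactly 6 nt apart more often than at neighbouring distances, with 2151 and 3713 such pairs in the control libraries and 5572 and 3857 with ascorbic acid, against 1091 to 1231 pairs at 5, 7 or 8 nt.

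**Figure D5:**
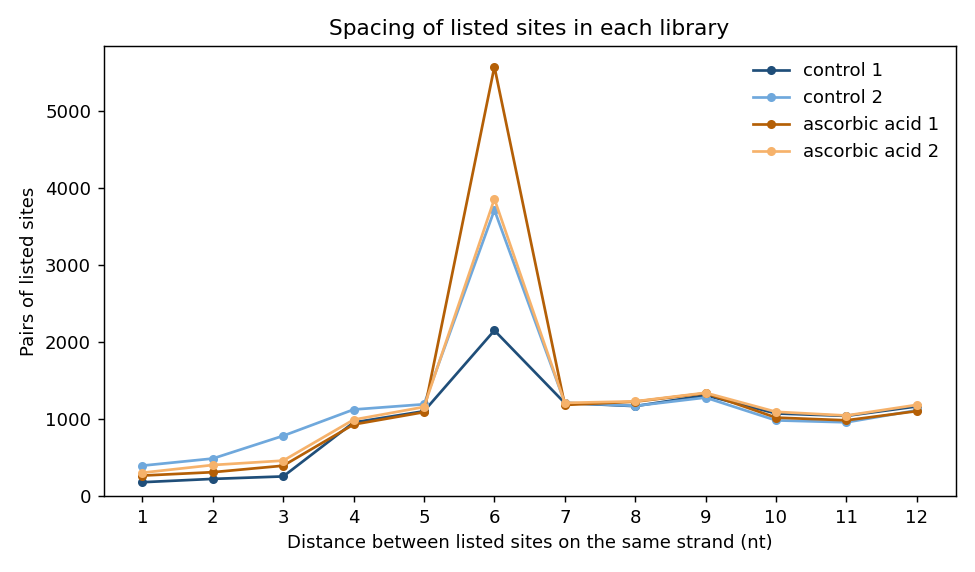
Number of pairs of listed sites on the same strand (y axis) by the distance between them (x axis, nt), 1 line per library. At 6 nt the libraries hold 2151 to 5572 pairs, and at 5, 7 and 8 nt 1091 to 1231.

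Gene coverage, which no source defines and which was taken from its header and values as mean read coverage per gene, stood in for transcript abundance and covers only genes with a listed site. Few genes changed. HMOX1, the heme oxygenase that releases iron from heme, rose from a scaled coverage of 255 ± 5.82 to 453 ± 26.9 (SD, n = 2, 1.78-fold, limma adjusted p = 0.0175). HSPB1, a small heat shock protein gene, rose from 465 ± 53.5 to 820 ± 39.9 (1.77-fold), ZCCHC12 from 141 ± 3.91 to 259 ± 0.398 (1.84-fold), SPATA20 from 56.7 ± 0.276 to 96.5 ± 7.32 (1.70-fold) and the apolipoprotein gene APOC1 from 126 ± 3.36 to 214 ± 14.3 (1.70-fold). UNCX and SP9, transcription factor genes, fell from 57.5 ± 2.23 to 33.9 ± 0.287 (0.591-fold) and from 55.7 ± 2.35 to 37.9 ± 0.658 (0.681-fold), and HIKESHI, a heat shock import factor gene, from 291 ± 3.74 to 207 ± 4.57 (0.710-fold). RNU2-1 fell from 117 ± 4.20 to 49.3 ± 7.38 (0.419-fold) and RNU2-23P from 270 ± 17.7 to 121 ± 3.12 (0.448-fold), but these near-identical copies of U2 RNA can share reads. FTO stood at 146 ± 1.18 in control and 185 ± 8.00 with ascorbic acid (1.27-fold, limma adjusted p = 0.0901) and ALKBH5 at 654 ± 44.3 and 594 ± 0.769 (0.908-fold, limma adjusted p = 0.411), neither past the threshold. METTL3 (fold 0.995), METTL14 (0.987), WTAP (1.00) and MALAT1 (0.995) did not pass either.

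Over 11848 genes limma called 30 higher and 5 lower, with 1710 at an unadjusted p under 0.05. The edgeR test, on another measure and gene set, the A plus G reads summed over the tested sites of 10782 genes, called 0, with 1013 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0806, and the limma count went to 71 when coverage was scaled by library totals and to 266 without control 1, 17 without control 2, 22 without ascorbic acid 1 and 18 without ascorbic acid 2. HIKESHI and SP9 lost their calls without control 2 or either ascorbic acid library, SPATA20 without control 2 and HSPB1 without ascorbic acid 2.

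The lists showed coverage changes of small size. In the collagen list COL6A1 rose 1.56-fold, from 94.3 ± 1.24 to 147 ± 3.34, and 21 of 22 genes did not pass (5 higher when adjusted over the list alone), while camera called the list higher (adjusted p = 0.00445, and adjusted p = 0.596 with an estimated correlation). In it LOXL1 stood at 23.8 ± 0.315 and 32.6 ± 1.68 and PLOD3, a lysyl hydroxylase gene, at 230 ± 0.706 and 285 ± 1.14. In the antioxidant response HMOX1 rose and 17 of 18 genes did not pass (3 higher adjusted over the list alone), with camera higher (adjusted p = 0.0248, and adjusted p = 0.785 with an estimated correlation). In iron handling HMOX1 and FBXL5, the gene of an iron-sensing ubiquitin ligase subunit, rose, FBXL5 from 128 ± 0.427 to 207 ± 6.70 (1.61-fold), and 24 of 26 genes did not pass (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0507). In the hypoxia list NDRG1 rose from 108 ± 0.911 to 153 ± 4.23 (1.42-fold) and 28 of 29 genes did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.155), with SLC2A1 at 390 ± 11.4 and 325 ± 6.70.

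No member of the remaining lists passed with limma. Counts of unadjusted p-values under 0.05 hold both directions, and over all 11848 genes they numbered 1710. Camera called the p53 targets higher (adjusted p = 0.00593, and adjusted p = 0.596 with an estimated correlation), with TP53I3 at 39.4 ± 0.225 and 55.4 ± 2.33 and CDKN1A, a cell cycle inhibitor gene, at 516 ± 13.5 and 615 ± 39.7; 6 of 21 genes had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone. Cholesterol synthesis was called lower (adjusted p = 0.0139, and adjusted p = 0.596 with an estimated correlation), with 4 of 21 genes at an unadjusted p under 0.05. ZNF genes were called lower (adjusted p = 0.0209, and adjusted p = 0.785 with an estimated correlation). Of these, 24 of 319 genes had an unadjusted p under 0.05, a smaller share than over all genes. Among the 4 of smallest p, ZNF22 (1.26-fold) and ZNF385A (1.19-fold) stood higher and ZNF706 (0.875-fold) and ZNF551 (0.859-fold) lower. Unadjusted p-values under 0.05 were found for 2 of 12 writers, 1 of 17 readers, 3 of 12 nucleic acid dioxygenases (FTO passed adjusted over the list alone), 1 of 24 JmjC dioxygenases, 2 of 12 ascorbate genes (1 lower adjusted over the list alone), 3 of 23 stress response genes, 8 of 23 transcripts studied as m6A targets, 3 of 30 cell cycle genes, 0 of 7 nuclear long noncoding RNAs and 10 of 100 ribosomal protein genes. Camera passed for none of these lists (adjusted p from 0.304 to 0.951). The calls for the antioxidant and ZNF lists were lost without control 2 (adjusted p = 0.389 and 0.477) or ascorbic acid 2 (0.106 and 0.202), and that for cholesterol synthesis without control 2 (0.0623) or ascorbic acid 1 (0.106).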

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

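The tests of sites 6 nt apart, of stretches with many listed sites and of depth were chosen after the rises had been seen. Sites on the mitochondrial genome, of which 3 were listed in all 4 libraries and the others could not be tested site by site, were listed 29 times in ascorbic acid 1 and 17 times in ascorbic acid 2, against 9 and 16 times in the control libraries. Their median level was 12.3% and 16.1% with ascorbic acid and 11.6% and 11.7% in control, and 16 of the 29 and 6 of the 17 had another listed site exactly 6 nt away, against 0 and 8 in control.

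The 172 sites that rose against the general fall share that spacing, since 72.1% of them had a listed site exactly 6 nt away. The 124 with such a partner had median levels of 11.4% and 15.3% in the control libraries and 19.5% and 16.1% with ascorbic acid. Ascorbic acid 2 thus lay little above control 2. The number of pairs 6 nt apart differed between replicates by a ratio of 1.73 in control and 1.44 with ascorbic acid. Pairs at 5, 7 or 8 nt differed by at most 1.08. The fewer pairs at 1 to 3 nt differed by up to 3.05 in control and 1.298 with ascorbic acid. The pairs, and not those at 6 nt alone, thus vary between libraries of 1 group. A source of most rises in library making or site calling is possible but was not tested. Incomplete conversion in stretches with many listed sites is argued against, on few sites, for the 124 rises with a partner at 6 nt. Of these, 3 had a neighbour at other distances within 10 nt, 0.314 times the share of like sites (exact binomial p = 0.0264). With the partner counted, 77.9% of all rises had a listed site within 10 nt, against 19.8% of sites of like level. Of the 48 without a partner 10 had a neighbour, 1.56 times the share of like sites and too few to decide (exact binomial p = 0.136). Within 2 nt, a limit other than the 10 nt set for this test, 4 of the 48 had one (8.33% against 0.721%, exact binomial p = 0.000408). That excess goes with it for those 4, but the binomial test counts close sites as independent though they can share reads. For the 124 rises with a partner at 6 nt the median depth was 1295 reads, against 172 at sites of their kind and level. Across all rises the median depth was 5.29 times that of sites of like level. Passing the test takes depth, as called falls were 3.19 times as deep as sites not called at those levels. The rises were chosen by passing it, so their depth cannot decide whether they are a random excess. This holds for the 124 rises and for the 48 with no partner at 6 nt. The median of those 48 was 109 reads, against 107 at sites of their own level. Open remain those 48 rises, which went from 23.5% and 25.96% in the control libraries to 39.1% and 39.4%, and the origin of the pairs: the cDNA adapter carries 6 random bases per the labels' protocols, so untrimmed or shifted ends are possible, as is site calling, and the reads or the sequence would be needed; an effect of ascorbic acid on these sites stays open as untested.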

How the results depend on the processing

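Settings that left out sites 6 nt from another listed site, sites in no named gene or sites on other contigs, the crossed pairing and the other sets for the conversion rate were chosen after the data were seen. At least 98.3% of the sites called in each setting were lower with ascorbic acid, and the count of genes that fell stayed within 1.5 times in every setting run. Sites called numbered 13333 (13172 lower) with at least 100 reads, where fewer sites are tested, 10501 (10476 lower, 25 higher) with limma and 9851 (9837 lower, 14 higher) with DESeq2, and 12528 to 17006 (12407 to 16969 lower, 28 to 237 higher) without 1 library, the lowest without ascorbic acid 2; the cause was not tested. Sites that rose numbered 50 in a quasi-binomial model, 265 after subtracting the unconverted share, 36 at mean levels of at least 0.3, 95 among sites listed in at least 1 library of each group and 56 without sites 6 nt from another. Genes that rose numbered 12 with at least 3 tested sites, 51 after subtraction, 19 with limma, 10 without sites 6 nt from another and 16 to 98 without 1 library, and the log2 odds turned to -0.60 in TRA2B, -0.59 in CERS2, -0.31 in ATIC, -0.65 in POLD1 and -0.71 in GSTA4 without those sites, which carry their rises.

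The difference of medians was -2.79 points over each library's own list, where the sites differ between libraries, and -6.17 to -7.91 points in the settings other than that list and the block. Sites listed in control only and ascorbic acid only numbered 4159 and 3875 at 50 reads or more, and 6352 and 3415 at levels of at least 0.2. With at least 50 reads, where fewer sites are left, the change was -4.94 points in long noncoding RNA genes and -3.86 points in no named gene. The difference in unconverted share was -0.402 points, -1.08 points without control 1 and 0.282 points without control 2.

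The replicate numbers share only a number, since same-numbered deviations correlated at -0.00535 over site log odds and -0.163 over coverage. With them as a block 21060 sites passed, the level changes were -6.09 and -7.99 points within numbers 1 and 2, 1 list of m6A level passed (ribosomal proteins, not collagen), and 92 genes changed coverage (70 higher, 22 lower); the crossed pairing gave 107 (85 higher, 22 lower). The cause was not tested.

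For coverage, 71 genes passed when scaled by totals (66 higher), 2 were lower among genes with coverage of at least 50, and edgeR on A plus G reads called 0, 0 higher and 0 lower, with 1013 at an unadjusted p under 0.05. Without 1 library 17 to 266 passed (11 to 182 higher, 4 to 84 lower), with 266 without control 1; the lone library of a group is then assumed to vary like the other group. The calls of lists fell to 0 for level and 0 for coverage with an estimated correlation, and to 1 to 2 and 3 to 6 without 1 library. Coverage changes near 0 changed sign, at 0.0112 in MALAT1, 0.000172 in METTL14 and 0.0109 in METTL3 scaled by totals, at 0.10 in MALAT1, 0.24 in METTL14, 0.0138 in METTL3 and -0.0587 in WTAP with edgeR, and over -0.14 to 0.12 in MALAT1, -0.0551 to 0.0182 in METTL14, -0.0725 to 0.0571 in METTL3 and -0.0893 to 0.0969 in WTAP without 1 library. Sites in the DRACH motif alone and transcript regions were not run. At single sites 35% of simulated changes of 1 in log2 odds were recovered, in data where far fewer sites changed than in the real ones.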

Other observations

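The tests of incomplete conversion, of more conversion at every site and of the other splits were chosen after the fall had been seen, and so was the distance pattern itself; the tests of dilution, of position within genes, of clustered sites and of abundance were set before their own results were seen. Further genes past the coverage threshold, named after their values were seen, included the secreted or matrix protein genes SPARC, from 147 ± 0.149 to 230 ± 6.08 (SD, n = 2), COL6A2, from 41.2 ± 2.56 to 60.6 ± 0.713, and CLU, from 139 ± 5.71 to 203 ± 3.62, with limma adjusted p = 0.0175, 0.0431 and 0.0329. The histone genes H2BC12, from 265 ± 8.97 to 406 ± 10.1, and H2AC6, from 25.1 ± 1.67 to 41.2 ± 2.99, belong to a family of near-identical copies and are uncertain. PCK2, a mitochondrial enzyme gene of gluconeogenesis, went from 66.7 ± 2.04 to 109 ± 2.04, and DUSP1, a phosphatase gene of stress signalling, from 136 ± 4.004 to 189 ± 2.88. CLU had no site compared, and none of the others passed with edgeR on A plus G reads summed over tested sites, which called 0 of 10782 genes, with 1013 at an unadjusted p under 0.05.

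The fall of m6A across most sites was not removed by the unconverted share: after subtracting it per gene the medians still fell by 7.02 points, and control 1 had the lowest unconverted share of the 4 libraries, which argues against poorer conversion in control. A reaction that converted more methylated A everywhere with ascorbic acid would scale all levels alike, and the share of the level that was kept did lie between 0.824 and 0.882 from 20 to 95% in control, but sites above 95% kept more than those at 40 to 60%, by 0.0536 or more in each pairing of libraries, and sites beyond 20000 nt from the 3' end kept less than nearer ones at 60 to 90%, by 0.108 or more, which argues against an even conversion as the whole cause and leaves one that differs by position open. Genes with a larger rise in coverage lost more (Spearman rho -0.176 across genes, which are not independent replicates). Dilution by newly made transcripts may therefore add to the fall, but the relation does not tell which change came first. Whether dilution is the only cause is not decided: 5386 genes whose scaled coverage was lower had a median change of -0.34 in log2 odds, and the bound set for this was wrong, as scaling centres coverage per library and so hides absolute amounts. Of the 3 splits of the 4 libraries into pairs 1 gave as many sites, the real one with 20313, and the highest other gave 0 by edgeR and by limma (234 and 300 sites at an unadjusted p under 0.05), but 3 splits are too few for a share under 0.05. Each other split put 1 control and 1 ascorbic acid library in both groups, so the treatment difference became spread within groups. Low counts there were built in, so the splits do not tell whether the real count arose by chance. A loss of methylation with ascorbic acid, through demethylases or through writing, stays open as a hypothesis, as does any difference in handling between the groups, which the labels do not describe.

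Sites far upstream of the annotated 3' end fell most, and 81.8% of the protein-coding sites that fell by more than 50 points lay beyond 5000 nt, against 30.3% of those that fell by up to 10 points. That genes with long spans simply lost more was tested within 414 genes that hold sites at 60 to 90% both under 5000 and over 20000 nt from the end: the change at far sites minus that at near sites had a median of -9.12 points (95% bootstrap interval -11.6 to -7.27), and 302 genes showed that direction. The position of a site within its gene may therefore matter. The interval covers the spread between genes in these 4 libraries, not that between samples. Choosing sites on control 1 and measuring against control 2 gave -9.01 points in 408 genes, which argues against chance highs in the chosen sites. Whether the far sites lie in introns of unspliced RNA, in alternative ends or in overlapping genes was not tested, as no transcript annotation was at hand.

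As further hypotheses, sites with another listed site within 10 nt may fall less than isolated ones. This held in 9 of 9 bins of mean level, and also in 9 when sites with a partner at 6 nt were left out. The medians differed little, from -8.25 against -8.38 points at 50 to 60% to -0.714 against -2.11 points at 10 to 20%. Bins of the same 4 libraries are not replicates, and distance to the 3' end was not held fixed. More abundant transcripts may lose less m6A, as control coverage and the change in log2 odds had a Spearman rho of 0.146 across 10782 genes, a weak relation. The control m6A level and that change had a stronger Spearman rho of -0.393, and level was not held fixed for abundance.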
